A study of Mus musculus with 9 samples.

How the data were processed

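Gene expression was measured in satellite cells sorted by flow cytometry from skeletal muscle of Bmi1-deficient and wild type FVB mice, 2 months old and labelled male. Per the labels' protocols, cells positive for integrin alpha-7 and CD34 and negative for CD31, CD45, CD11b and Sca1 were collected in lysis buffer, and their RNA was amplified by whole transcriptome amplification, since a sort gives little RNA. Amplification can distort the level of a transcript in the same way in every sample, so a level was not read as an amount of RNA. The cDNA was labelled with Cy3 and hybridised to Agilent arrays of 1 colour with 62976 spots each, of which 59305 are not controls and hold 55681 probes.

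The authors deposited the scanner output of each of the 9 arrays, with spot intensity on a linear scale. Per the file headers, Agilent Feature Extraction subtracted the background from the processed signal, corrected spatial trends and replaced dim values by a small positive surrogate, with no normalization between arrays. A surrogate makes the fold of a gene near background unreliable. A gene not well above background on any array of a group is therefore given with a bound. Genes well above background on only some arrays of a group have no bound, and their folds are uncertain too. The authors also deposited a table of processed values per probe, which is on a log2 scale by its range. Its columns shared a median of 7.806, as quantile normalization gives, and matched a normexp correction with an offset of 50 followed by quantile normalization (r of 0.999976 over probes, largest difference 0.0569), each best with its own array. The method of that table is not given in the sources used here, so its scale and background correction are known from this match only, and it was used as an alternative. Values were not centred per gene.

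Here, the log2 of the processed signal was taken and each array's 75th percentile over non-control spots subtracted. Spots with an outlier mark, 93 to 148 per array, were left out, repeat spots of a probe were averaged, and 35 probe values that this left empty on an array were filled with the probe's mean over the other arrays. Probes well above background on at least 3 of 9 arrays were kept, which left 42983 and removed 12698. Since 6 of the 9 arrays are KO, a gene present only in KO passes this filter more easily than one present only in WT. Probe names were updated through a RefSeq table of the assembly GRCm38, used for names alone: 26300 probes matched by accession, 2044 by symbol and 355 by synonym, and 26982 kept the name in the files. For each gene the kept probe with the highest mean over all arrays was used. Other kept probes gave 4.85 for Tfap2a, 1.02 and 2.15 for Cdkn1a, 2.52 for Flt1, -0.74 for Rpl21, 0.89 for Tnc, 1.11 for Trdn, 0.99 and 0.49 for Mbp, 3.44 for Zic1, 1.27 for Cxcl12, and -0.10 and -0.01 for Hspa4, and some other named genes also have probes that differ. Coordinates are those of the array design, in mm9. The strand that the labelling preserved is not given in the sources used here.

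KO arrays whose descriptions share a first number were averaged and counted as 1 sample, because they differed by about the scatter of repeat spots. The design fixed before the data were examined treated all 9 arrays as separate samples, with this averaging as an alternative. Averaging became the main analysis after the arrays were compared, and the counts of changed genes under both were known by then (40 and 1202). The gene lists, the rule for naming genes and most alternatives were also fixed before the data were examined. The fits of all 9 arrays and those that leave out a whole KO sample are alternatives chosen after seeing the data. The rule for the Hox pattern was changed after its results were seen. A version that asked for the trend among the 25 genes well above background on all arrays (rho 0.278, permutation p = 0.178) was dropped, since a rise from a dim WT level itself removes a gene from that set.

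WT and KO were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (with the packages data.table, version 1.17.8, and statmod 1.5.0), 3 samples against 3, and p was adjusted by Benjamini and Hochberg over 28365 genes and features, 16774 of them with a symbol, at a threshold of 0.05. There were 4 residual degrees of freedom and 2.04 from the prior. Bmi1, Cdkn2a and Cdkn2b were also tested by an exact two-sided permutation test over the 20 splits of the samples. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the plots. Lists of 1043 genes in all, 942 of them measured, were written for pathways and for markers of the other cell types that the gate could hold. Each of the 32 lists with at least 5 measured genes was tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and fry as alternatives. A further list of genes of the sex chromosomes was set aside as a check.

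The text names Bmi1, Cdkn2a and Cdkn2b, then in each direction the 10 genes with a symbol and the largest change among those that passed and whose arrays do not overlap. Where fewer than 5 passed, it names the 5 with the smallest unadjusted p and no overlap. From each list it names up to 4 members with the smallest unadjusted p, and some of these are not reported here. The other GATA factors, Dlx1, Pdgfra, Pax7, Myf5, Myod1, Myog, Loxl1, Fabp4, Ly6c1, Kdr and Tek were chosen after their values were seen. A log2 change is KO minus WT, with its standard error, n is the number of samples, and samples are said to be apart, or not to overlap, where all 3 of one group lie above or below all 3 of the other.

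Both steps were tested on simulated data with known answers. With 28365 genes and 200 changed in each of 5 runs of 3 samples against 3, limma called 27.6% of genes changed by a log2 of 1, 71.2% at 2, 85.2% at 3 and 89.6% at 4, and 4.47% of its calls were false. Camera called 0 lists without a shift, and 31 of 32 lists shifted by 0.5 with the preset correlation and 20 with an estimated one. These simulated genes were independent, which favours the preset correlation.

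The alternatives were other background corrections, scalings and filters, the deposited table, the mean of a gene's probes, slide or replicate number as a block, array weights, a trended and robust prior, each array or sample left out, and KO replicate 1 as WT. Scan followed slide, so the same block serves both. No sample was left out of the main comparison.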

Results

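The series measured gene expression in satellite cells, the stem cells of skeletal muscle, sorted from muscle of Bmi1-deficient (KO) and wild type (WT) mice of the FVB strain, labelled male and 2 months old. Bmi1 is a subunit of Polycomb repressive complex 1, which keeps developmental genes and the Cdkn2a locus silent. The comparison asks which genes differ in satellite cells that lack Bmi1, in a series on loss of quiescence and senescence of muscle stem cells in geriatric mice. There were 9 arrays of 1 colour (Cy3), 3 of WT and 6 of KO. The 6 KO arrays formed 3 pairs that shared a number in their descriptions, and the arrays of a pair differed far less (r from 0.9963 to 0.9974 over probes) than any of the 33 other pairs of arrays (r from 0.9735 to 0.9863). The scatter of 1 array within these pairs, an SD of 0.135 to 0.157 on the log2 scale, was close to that between repeat spots within an array (0.102 to 0.131). Each such pair was therefore averaged and counted as 1 sample, which left 3 WT and 3 KO samples (KO sample 1 from replicates 1 and 4, sample 2 from 2 and 5, sample 3 from 3 and 6).

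Signal was similar on all arrays. Between 71.9% and 75.8% of the 59305 non-control spots were well above background, the median processed signal lay between 148 and 202, and 0 spots were saturated. The number of arrays limits the precision. The labels call the arrays biological replicates, but nothing says that the samples came from separate animals, so p-values measure only the spread between these samples, which may be technical. KO replicate 1 is KO by title, source and description, while its genotype field says wild type, and it was kept in the KO group. It matched KO replicate 4 with an r of 0.9971, as compared to 0.9764, 0.98 and 0.9735 with WT replicates 1, 2 and 3. Its log2 signal of Cdkn2a was -0.88, with -0.95 in KO replicate 4 and -4.28, -4.23 and -3.64 in the WT replicates. These values argue against the wild type entry. The arrays lay on 2 slides, with 2 WT and 3 KO arrays on slide 1 and 1 WT and 3 KO arrays on slide 2. Each comparison is therefore also given within each slide and with slide as a block. Each KO sample averages an array of each slide, so the slide term of this block is set by the WT samples alone. With 1 WT array, slide 2 has no spread of WT, so its values are given without a test.

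The targeted gene was not lower in the samples labelled KO. Both Bmi1 probes (chromosome 2, 18607531 to 18607590 and 18607987 to 18608046, mm9) were well above background on all 9 arrays. At the first, the normalised log2 signal of the 3 WT samples was 0.40, 0.61 and 0.48, and that of the 3 KO samples was 0.58, 0.71 and 0.48. The means were 0.49 ± 0.11 in WT and 0.59 ± 0.12 in KO (SD, n = 3 each), a difference of 0.10 (exact two-sided permutation p = 0.4). The second probe differed by 0.21 (exact permutation p = 0.2). With 3 samples against 3, this test cannot give a p below 0.1. Within slide 1, within slide 2 and with slide as a block, Bmi1 differed by 0.05, 0.10 and 0.07. The deleted part of the gene is not given in the sources used here, and a probe outside it checks nothing. The labels therefore have no check from the Bmi1 transcript, and every direction below is that of the samples labelled KO over those labelled WT.

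Cdkn2a, which encodes the cell cycle inhibitor p16Ink4a and the p53 activator p19Arf and is the best known target of Bmi1, rose 9.72-fold in KO (log2 difference 3.28 ± 0.21, SE; limma adjusted p = 0.0157). Its log2 signal was -4.05 ± 0.35 in WT and -0.77 ± 0.18 in KO (SD), and the lowest KO sample (-0.92) lay far above the highest WT sample (-3.64). The exact permutation p was 0.1, the smallest that the design allows. The probe (chromosome 4, 88920405 to 88920464) was well above background on all 9 arrays, while a second Cdkn2a probe (88920543 to 88920602) was well above background on 1 of 9 and differed by 0.69 (exact permutation p = 0.3). The difference was 3.17 ± 0.24 within slide 1 (limma adjusted p = 0.106), 3.48 within slide 2 and 3.33 ± 0.23 with slide as a block (0.0696). These were of similar size but with no call in either test, and both tests leave fewer degrees of freedom. The slide term of the block is also set by the WT samples alone. A fit chosen after the data were seen used all 9 arrays, sample as a random block and slide as a fixed block. There Cdkn2a differed by 3.28 ± 0.20 and passed (limma adjusted p = 0.00146). That fit takes its degrees of freedom from arrays and not from samples, so its p may be too small. The neighbouring inhibitor Cdkn2b (88952276 to 88952335) differed by 0.59 ± 0.32, which did not pass (limma adjusted p = 0.586), with 0.62, 0.52 and 0.57 in the same 3 slide settings (within slide 1, within slide 2 and with slide as a block, in this order below). Its second probe differed by 0.39.

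**Figure D1:**
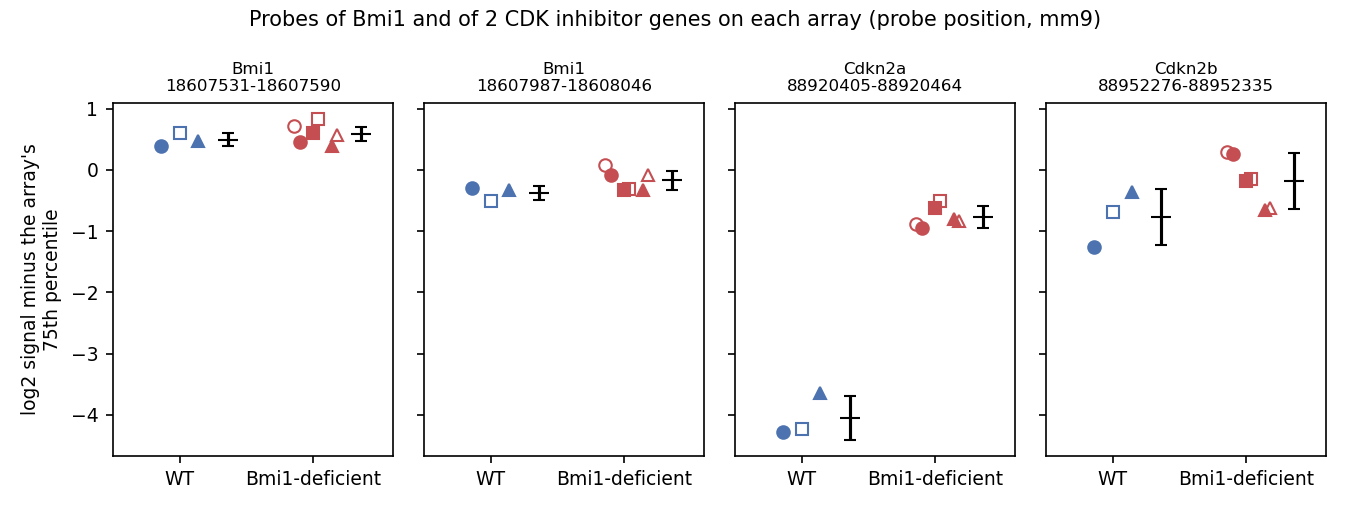
Normalised log2 signal of each array (y axis) for both Bmi1 probes, Cdkn2a and Cdkn2b in WT and KO (x axis). Points are arrays, with a shape for each sample and filled or open by slide, and the bars give the mean and SD of the 3 samples of a group. The KO points of Cdkn2a lie well above those of WT (means -0.77 and -4.05), while the groups overlap for Bmi1.

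Of the 7 CDK inhibitors measured, Cdkn2a alone passed, over all genes and adjusted over the list alone. The others with the smallest p were the p53-induced Cdkn1a (0.70), Cdkn2c (-0.75) and Cdkn2d (-0.48). Other Cdkn1a probes gave 1.02 and 2.15. The list did not shift (median -0.11, mean 0.41, limma's camera adjusted p = 0.386), though it moved upward by limma's fry (adjusted p = 0.0458), which does not compare its genes with others, and its median and its mean and test had opposite signs. Samples did not overlap in 57.1% of its genes, 2 higher and 2 lower, as compared to 16.7% of all genes. Chance gives 10%, and shares of the lists below are also to be read against that of all genes. Among the other Polycomb subunits, 13 of 30 were higher and 17 lower, and the list did not shift either (median -0.06, adjusted p = 0.339). The limma count was 0 over all genes and adjusted over the list alone, with 6 members at an unadjusted p under 0.05. They included Pcgf6 (-0.55), Ezh2 (-0.64) and Phf19 (-0.81). The medians of the CDK inhibitors and of the Polycomb subunits were -0.01 and -0.07 within slide 1, -0.08 and -0.09 within slide 2, and -0.18 and -0.10 with slide as a block.

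Over 28365 genes and unnamed features limma called 40, of which 37 rose and 3 fell, and 30 have a gene symbol. The log2 change of those called ranged in size from 1.29 to 6.45, and WT was not well above background for 10 of them. At an unadjusted p under 0.05 there were 3116. The 3 samples of one group did not overlap those of the other in 16.7% of all genes, where chance gives 10%, and in all 40 called ones. The count depended on every sample. Without WT sample 1, 2 or 3 it was 0, 1 and 0 (limma, with 2558, 3235 and 2536 genes at an unadjusted p under 0.05), and without KO sample 1, 2 or 3 it was 5, 9 and 1. It was 2 within slide 1 and 4 with slide as a block, whose slide term is set by the WT samples alone. Those called within slide 1 were St8sia4 and a probe without a gene name, A_66_P120612 (5.03), and those with slide as a block were Tfap2a, Hoxc13, this probe (5.74) and A_55_P2315762 (2.62). Without WT sample 2 the gene left was A_66_P120612, and without KO sample 3 it was Hoxc13. With all 9 arrays as separate samples the count was 1202 (893 higher, 309 lower), and with the sample as a random block 546. With slide as a fixed block added to the random block it was 367. Fits of separate arrays take their degrees of freedom from arrays and not from samples, so these counts may be too high.

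Tfap2a, a factor of neural crest and epidermis, rose by 6.45 ± 0.46 (limma adjusted p = 0.0237) and was at least 31.7-fold higher in KO. It was not well above background on any WT array, so its fold is a bound: the KO mean was set against the mean, over WT arrays, of the higher of the lowest signal well above background and the probe's own. Its second probe gave 4.85. Hoxc13, which acts in hair follicles and nails, rose by 5.70 ± 0.24 (at least 13.6-fold), and Hoxd13, which patterns the digits, by 5.47 ± 0.29 (at least 12.2-fold). The mesenchymal forkhead factor Foxf1 rose by 3.71 ± 0.23 and Onecut2, a factor of liver and neurons, by 3.61 ± 0.28 (12.2-fold). The adhesion receptor Adgrg1 rose by 3.38 ± 0.34, the homeobox gene Irx2 by 3.1 ± 0.29 and St8sia4, an enzyme of polysialic acid synthesis, by 2.89 ± 0.28 (at least 2.70-fold). Foxf1, Adgrg1 and Irx2 were well above background on 1 of 3 WT arrays. Zic1, a zinc finger factor of somites and the nervous system, rose by 2.66 ± 0.17 (6.33-fold), and by 3.44 at its second probe. These 9 genes had limma adjusted p between 0.00993 and 0.0444, as had Cdkn2a, the other of the 10 higher genes that the fixed rule names.

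The sizes depend on the background correction. After normexp with an offset of 50, which pulls dim values together, and the 75th percentile, the log2 change was 3.08 for Tfap2a, 2.14 for Hoxc13, 1.95 for Hoxd13, 1.79 for Foxf1, 2.93 for Onecut2, 1.36 for Adgrg1, 1.27 for Irx2, 0.58 for St8sia4, which was not called there, 2.58 for Zic1 and 2.48 for Cdkn2a. The folds and bounds above thus hold for background-subtracted signal only. All these genes kept their direction within each slide. With slide as a block Tfap2a (6.22, limma adjusted p = 0.0477) and Hoxc13 (5.72, adjusted p = 0.0477) still passed, and Hoxd13 (5.54), Foxf1 (3.76), Onecut2 (3.53), Adgrg1 (3.22), Irx2 (2.99), St8sia4 (2.75) and Zic1 (2.64) did not. That slide term is set by the WT samples alone. With all arrays kept separate, sample as a random block and slide as a fixed block, each of these genes passed. The highest limma adjusted p there was 0.0448, for St8sia4. Since that fit takes its degrees of freedom from arrays and not from samples, these p may be too small. Within slides 1 and 2 the changes were 6.94 and 5.50 for Tfap2a, 5.62 and 5.82 for Hoxc13, 5.27 and 5.81 for Hoxd13, and 3.61 and 3.91 for Foxf1. They were 3.74 and 3.32 for Onecut2, 3.57 and 2.87 for Adgrg1, 3.35 and 2.62 for Irx2, 3.17 and 2.33 for St8sia4, and 2.75 and 2.53 for Zic1. The probes of the genes lie at 40811044 to 40811103 of chromosome 13 (Tfap2a), 102759058 to 102759117 of chromosome 15 (Hoxc13), 74509248 to 74509307 of chromosome 2 (Hoxd13) and 91257301 to 91257360 of chromosome 9 (Zic1), in mm9.

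Other developmental genes under Polycomb control shifted upward as a list, as did markers of endothelial, mesenchymal, mural and glial cells in the same samples (medians 1.27, 0.80, 0.63 and 0.76; adjusted p = 0.271, 0.0841, 0.255 and 0.0867 with an estimated correlation). Of 74 such genes listed, 45 were measured, 31 of these were higher in KO and 14 lower, and the shift passed (median 0.26, mean 0.69, camera adjusted p = 8.42e-06; adjusted p = 0.0786 with an estimated correlation). Over all genes 2 passed, Foxf1 and Zic1, and adjusted over the list alone 12 were higher and 1, Dlx1 (-1.03), was lower. The GATA factors Gata4 (2.28), Gata2 (3.65) and Gata6 (2.77) were not well above background in WT and were at least 4.00-fold, 4.10-fold and 4.06-fold higher in KO on background-subtracted signal, with Gata4 at 0.65 and Gata2 at 0.97 after the normexp correction. The groups were apart in 46.7% of the members, and the list's median was 0.24, 0.35 and 0.29 above the WT mean in KO samples 1, 2 and 3. It was 0.29 within slide 1, 0.36 within slide 2 and 0.35 with slide as a block.

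Hox genes moved both ways. Of 33 measured, 17 were higher and 16 lower, and the list as a whole did not shift (median 0.04, mean 0.51, camera adjusted p = 0.446), though it moved upward by fry (adjusted p = 0.0345). Its medians were 0.03, 0.11 and 0.07 within slide 1, within slide 2 and with slide as a block. Over all genes Hoxc13 and Hoxd13 passed. Adjusted over the list alone Hoxa2 (-1.30 ± 0.16, limma adjusted p = 0.0635 over all genes), a gene of the hindbrain and branchial arches, and Hoxa3 (-0.79) were lower as well. Samples were apart in 51.5% of the Hox genes. The 9 genes numbered 1 to 4 had a median change of -0.15, with 3 higher and 6 lower, the 14 numbered 5 to 9 a median of 0.06 (7 higher, 7 lower), and the 10 numbered 10 to 13 a median of 0.78 (7 higher, 3 lower).

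**Figure D2:**
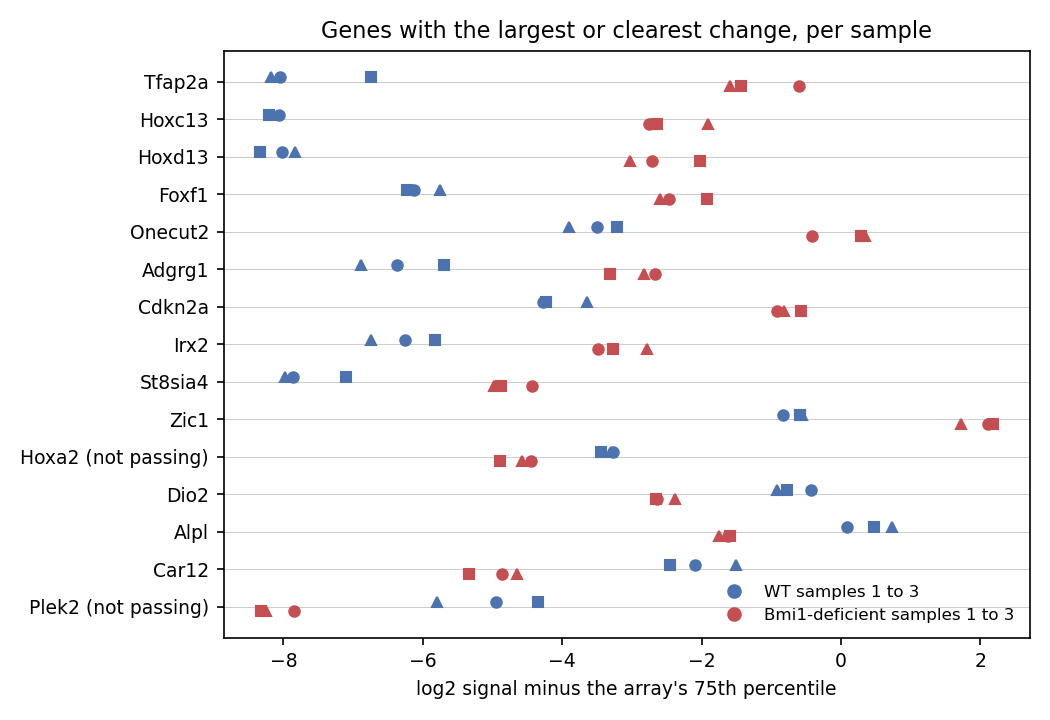
Normalised log2 signal (x axis) of the genes named by the fixed rule (y axis) in the 3 WT and 3 KO samples, 1 point per sample, which is the mean of its arrays. In Tfap2a, Hoxc13 and Hoxd13 the WT samples lie between -8.33 and -6.75 and the KO samples between -3.03 and -0.61.

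The 3 genes that fell were the tissue-nonspecific alkaline phosphatase Alpl (-2.09 ± 0.19, limma adjusted p = 0.0442), the thyroid hormone activating deiodinase Dio2 (-1.85 ± 0.17, adjusted p = 0.0444) and the membrane carbonic anhydrase Car12 (-2.93 ± 0.30, adjusted p = 0.0444). WT was 4.25-fold, 3.60-fold and 7.62-fold over KO, and Car12 gave -1.77, Alpl -1.89 and Dio2 -1.59 after the normexp correction. Hoxa2 and Plek2 had the next smallest p among genes lower in KO and did not pass. Plek2 differed by -3.12 ± 0.38 (adjusted p = 0.0635), with KO not well above background and WT at least 4.81-fold over it (-0.70 after normexp). Within slides 1 and 2 Alpl gave -2.22 and -1.98, Dio2 -1.85 and -1.82, Car12 -3.36 and -2.28, Hoxa2 -1.34 and -1.20, and Plek2 -2.59 and -3.99. With slide as a block, a term set by the WT samples alone, Alpl (-2.10), Dio2 (-1.83), Car12 (-2.82), Hoxa2 (-1.27) and Plek2 (-3.29) did not pass. All arrays were also fitted separately, with sample as a random block and slide as a fixed block. There Alpl (limma adjusted p = 0.00548), Dio2 (0.00442), Car12 (0.0139) and Hoxa2 (0.0227) passed, and Plek2 (0.111) did not. The degrees of freedom of that fit come from arrays and not from samples, so these p may be too small.

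Genes of mitosis were lower in KO. All 35 measured G2/M genes lay below WT, and the list shifted down (median -1.0, camera adjusted p = 3.19e-17; adjusted p = 0.255 with an estimated correlation and 0.102 by fry). Over all genes 0 passed in limma, 21 had an unadjusted p under 0.05, and 14 passed adjusted over the list alone, among them the mitotic ubiquitin enzyme Ube2c (-1.49), the kinetochore gene Nuf2 (-0.79), the anaphase activator Cdc20 (-1.18) and cyclin B1, Ccnb1 (-1.34). Samples did not overlap in 65.7%. The size differed between KO samples, with medians of -0.90, -0.36 and -1.62 against the WT mean, and it was -0.95 within slide 1, -0.99 within slide 2 and -1.0 with slide as a block.

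DNA replication genes and E2F targets were lower too. All 36 measured lay below WT (median -0.55, camera adjusted p = 3.52e-10; adjusted p = 0.409 with an estimated correlation and 0.213 by fry), and samples did not overlap in 38.9%. The limma count was 0 over all genes and adjusted over the list alone, with 6 at an unadjusted p under 0.05. They included the helicase subunits Mcm7 (-0.56) and Mcm5 (-1.04), the polymerase Pola1 (-0.67) and E2f2 (-0.64). Medians were -0.15, -0.35 and -1.17 in KO samples 1, 2 and 3, and -0.05, -0.13 and 0.17 in the WT samples. KO sample 1 thus lay close to WT sample 2, and KO sample 3 lay far lower than the others. The median was -0.62, -0.44 and -0.54 within slide 1, within slide 2 and with slide as a block. DNA repair genes also shifted down, with 28 of 32 lower (median -0.26, camera adjusted p = 8.42e-06; adjusted p = 0.255 with an estimated correlation and 0.093 by fry; samples apart in 28.1%). Of them 0 passed in limma over all genes or adjusted over the list alone, and 8 had an unadjusted p under 0.05, such as the DNA damage histone H2ax (-1.06), the mismatch repair gene Msh6 (-0.42), the recombination gene Rad54l (-0.85) and Parp1 (-0.54). Their median was -0.28 within slide 1, -0.20 within slide 2 and -0.26 with slide as a block.

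Among the secreted factors of senescent cells that were measured, most were higher. Listed members that were not measured included Il6, Il1a, Tnf, Cxcl5, Mmp3, Mmp9 and Mmp13. Of 46 listed, 33 were measured, 27 of them higher and 6 lower, and the list shifted upward (median 0.50, or 0.46 with a gene not well above background at its bound; camera adjusted p = 1.38e-07; adjusted p = 0.17 with an estimated correlation). In limma 0 passed over all genes, 15 had an unadjusted p under 0.05, and 5 passed adjusted over the list alone, among them the matricellular protein Ccn2 (2.69), the chemokine Cxcl12 (0.87) and the binding proteins Igfbp6 (0.80) and Igfbp7 (0.99). The groups were apart in 45.5%, and the median was 0.60 within slide 1, 0.26 within slide 2 and 0.42 with slide as a block. Markers of fibroblast-like cells were also higher in the same samples (median 0.80; adjusted p = 0.0841 with an estimated correlation), and 6 of the 33 genes stand in another list too. Targets of p53 shifted upward by less, with 23 of 32 higher (median 0.15, camera adjusted p = 0.00389; adjusted p = 0.255 with an estimated correlation and 0.11 by fry). Over all genes limma called 0, 5 had an unadjusted p under 0.05, and Phlda3 (0.96) and Perp (1.06) passed adjusted over the list alone. Btg2 gave 0.60 and Zmat3 0.48. Samples were apart in 21.9% of p53 targets, their median was -0.03, 0.32 and 0.27 in KO samples 1, 2 and 3, and 0.14, 0.22 and 0.14 in the 3 slide settings. Without KO sample 2 this shift did not pass (adjusted p = 0.136; from 2.78e-05 to 0.255 over all alternatives).

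Immediate-early genes, which respond within minutes to stress and to tissue dissociation, were higher in 33 of 35 cases, and the list shifted upward (median 0.43, camera adjusted p = 7.12e-13; adjusted p = 0.0841 with an estimated correlation). Limma called 0 over all genes, 16 had an unadjusted p under 0.05, and 8 passed adjusted over the list alone, among them Cebpd (1.45), Gadd45b (0.60), the nuclear receptor Nr4a2 (1.62) and Ier3 (1.19). Samples did not overlap in 57.1%, and the median was 0.53 within slide 1, 0.38 within slide 2 and 0.40 with slide as a block. Heat shock genes and chaperones went the other way, with 18 of 19 lower (median -0.19, camera adjusted p = 0.00399; adjusted p = 0.546 with an estimated correlation and 0.268 by fry; samples apart in 21.1%). By limma, 0 members passed over all genes or adjusted over the list alone, and 1, Hspb8 (0.87), the member that was higher, had an unadjusted p under 0.05. Hspa4 gave -0.33, Hspd1 -0.34 and Hspb1 -0.46. The shift was -0.29 within slide 1, -0.06 within slide 2 and -0.15 with slide as a block. It did not pass without WT sample 1 (adjusted p = 0.0595) or KO sample 1 (adjusted p = 0.0741), in a range from 0.000211 to 0.546 over all alternatives.

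Extracellular matrix genes shifted upward as a list. Of 42 measured, 40 were higher (median 0.58, camera adjusted p = 5.87e-17; adjusted p = 0.0786 with an estimated correlation). In limma 0 passed over all genes, 24 had an unadjusted p under 0.05, and adjusted over the list alone 19 were higher and 1, Loxl1 (-0.52), was lower. Elastin, Eln, gave 2.08 (limma adjusted p = 0.0544 over all genes), the adhesion modulator Tnc 1.88, and the chains of type I collagen, Col1a1 and Col1a2, 1.91 and 1.23. The groups were apart in 69% of these genes. The median was 0.69, 0.57 and 0.47 in KO samples 1, 2 and 3, and 0.67, 0.37 and 0.52 within slide 1, within slide 2 and with slide as a block.

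Markers of fibro-adipogenic progenitors, the resident mesenchymal cells of muscle, were higher in the same samples. Of 25 measured, 23 were higher (median 0.80, camera adjusted p = 1.9e-10; adjusted p = 0.0841 with an estimated correlation), and 10 of them stand in another list, as do 10 of the matrix genes. Over all genes limma called 0, 11 had an unadjusted p under 0.05, and 9 passed adjusted over the list alone, among them Smoc2 (0.88), Mfap5 (1.44) and Pdgfra, the surface receptor of these cells (2.93, at least 4.23-fold, on background-subtracted signal, over a WT level not well above background). Samples were apart in 52%. Medians were 0.78, 0.43 and 0.74 in KO samples 1, 2 and 3, and 0.75, 0.75 and 0.83 in the 3 slide settings. Tenocyte markers shifted upward too, with 9 of 11 higher (median 0.68, mean 1.10, camera adjusted p = 0.00153; adjusted p = 0.271 with an estimated correlation and 0.131 by fry; samples apart in 27.3%). Limma called 0 over all genes, 4 had an unadjusted p under 0.05, and Thbs4 (1.34) and Clec11a (0.68) passed adjusted over the list alone. The tendon matrix genes Comp (3.93 ± 1.17) and Fmod (3.0) had wide errors, and the median was 0.08, 0.83 and 1.18 in KO samples 1, 2 and 3, and 0.86, 0.59 and 0.67 in the 3 slide settings.

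Vessel and nerve markers were also higher. All 21 endothelial genes measured, of 24 listed, lay above WT (median 1.27, camera adjusted p = 5.61e-07; adjusted p = 0.271 with an estimated correlation and 0.138 by fry). By limma, 0 members passed over all genes and 6 had an unadjusted p under 0.05. Adjusted over the list alone 3 passed, the VEGF receptor Flt1 (1.27), Ecscr (1.64) and VE-cadherin, Cdh5 (1.48). Flt1 was well above background on 2 of 3 WT arrays, ranged from 0.32 to 1.89 over all alternatives and gave 2.52 at its second probe. Von Willebrand factor, Vwf, gave 0.73. Samples did not overlap in 19%. The median was 1.96, 0.14 and 1.31 in KO samples 1, 2 and 3 and -0.26, 0.46 and -0.17 in the WT samples, and it was 1.49, 0.59 and 1.20 in the 3 slide settings. Of pericyte and smooth muscle markers 16 of 17 were higher (median 0.63, camera adjusted p = 6.86e-07; adjusted p = 0.255 with an estimated correlation and 0.0695 by fry; samples apart in 47.1%). The mural cell receptor Pdgfrb rose by 1.35 ± 0.11 (limma adjusted p = 0.0377), and adjusted over the list alone 4 passed, with Cspg4 (0.67), Myl9 (1.12) and Abcc9 (1.07). KO samples 1, 2 and 3 gave medians of 0.92, 0.20 and 0.90, and the slide settings 0.69, 0.73 and 0.64.

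Schwann and glial cell markers were higher in 16 of 17 cases (median 0.76, camera adjusted p = 9.55e-08; adjusted p = 0.0867 with an estimated correlation). In limma 0 passed over all genes, 10 had an unadjusted p under 0.05, and 6 passed adjusted over the list alone, among them the myelin genes Mbp (1.38) and Mag (0.94) and the glial factor Sox10 (1.26). The groups were apart in 52.9%, with medians of 0.59, 0.75 and 1.09 in KO samples 1, 2 and 3 and 0.69, 1.11 and 0.87 in the 3 slide settings. Mature myofibre markers shifted upward as well, with 18 of 28 higher (median 0.31, or 0.28 with dim genes at their bound; camera adjusted p = 0.00731; adjusted p = 0.271 with an estimated correlation and 0.131 by fry; samples apart in 25%). Over all genes limma called 0, 6 had an unadjusted p under 0.05, and Trdn (2.07) and Mylk2 (1.55) passed adjusted over the list alone. The fast myosin Myh1 gave 0.96 and Ampd1 2.16 (at least 1.33-fold over WT on background-subtracted signal, and 0.35 after normexp). The median was 0.83, -0.02 and 0.15 in KO samples 1, 2 and 3, and 0.28, 0.35 and 0.32 in the 3 slide settings, and the shift did not pass without WT sample 2 (adjusted p = 0.0624) or without KO sample 1 (adjusted p = 0.0711; from 0.00149 to 0.271 over all alternatives).

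Blood cell markers did not shift over the 6 samples. Of 22 myeloid genes 8 were higher and 14 lower (median -0.08, mean -0.31, camera adjusted p = 0.228; samples apart in 22.7%), and without KO sample 3 the list passed downward (adjusted p = 0.0319; from 0.0319 to 0.546 over all alternatives). Limma called 0 over all genes, 2 had an unadjusted p under 0.05, and the lysosomal protease Ctss (-2.65) passed adjusted over the list alone, with KO not well above background and WT at least 3.63-fold over it on background-subtracted signal (-0.52 after normexp). Cd68 gave 0.45, Ccl6 -0.64 and Tyrobp -1.26. Of 12 lymphoid genes measured, of 20 listed, 2 were higher and 10 lower (median -0.14, adjusted p = 0.386; samples apart in 0%), with Cd2 at 0.56 and Lck at -0.41. Of 6 erythroid genes measured, of 14 listed, 3 were higher and 3 lower (median -0.02, adjusted p = 0.778; samples apart in 0%). Neither list had a gene that passed in limma over all genes or adjusted over the list alone, and the number at an unadjusted p under 0.05 was 0 in both. Medians within slide 1, within slide 2 and with slide as a block were -0.11, -0.11 and -0.09 for myeloid, -0.13, -0.09 and -0.10 for lymphoid, and 0.03, -0.13 and -0.08 for erythroid genes.

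**Figure D3:**
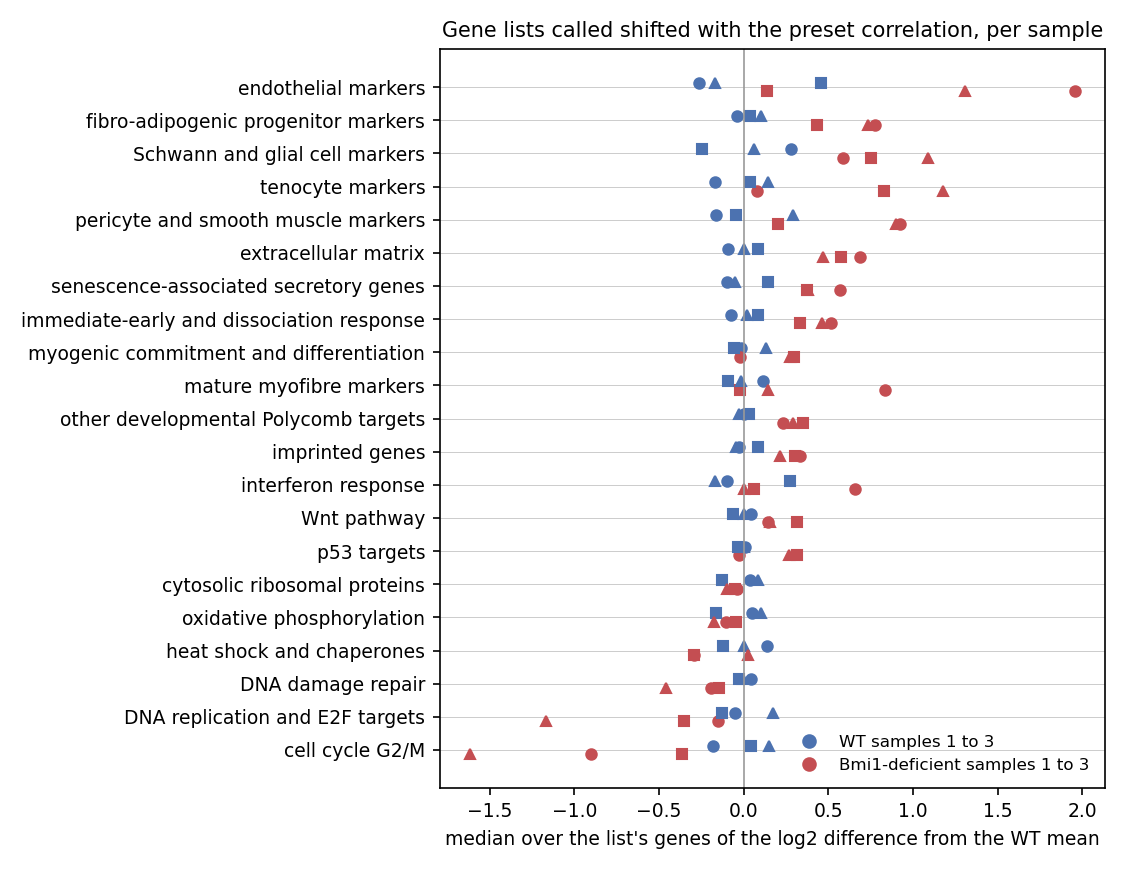
Median, over the measured genes of each fixed list (y axis), of the log2 difference from the WT mean (x axis), 1 point per sample. The G2/M median lies between -1.62 and -0.36 in the KO samples, and the endothelial median between 0.14 and 1.96.

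Pax7, the defining factor of satellite cells, differed by 0.02 ± 0.17 in KO and Myf5, a factor of the myogenic lineage, by 0.66 ± 0.48, and neither passed. Of 38 genes of satellite cell identity and quiescence, 25 were higher and 13 lower, and the list lay near the threshold without passing it (median 0.08, camera adjusted p = 0.0673). It passed within slide 1 (0.16, adjusted p = 0.0166) and not with slide as a block (0.06), and its median was 0.02 within slide 2. It also passed under 12 of 31 alternatives, among them quantile normalization (adjusted p = 0.00489), without WT sample 2 (adjusted p = 0.00786) and without KO sample 3 (adjusted p = 0.0211), in a range from 0.00297 to 0.546 over all alternatives. By limma, 0 members passed over all genes, 7 had an unadjusted p under 0.05, and the surface proteoglycan Sdc4 (0.75) and the paired box factor Pax3 (1.22) passed adjusted over the list alone. Ncam1 gave -0.44 and Foxo3 0.48, and samples did not overlap in 31.6%. Genes of myogenic commitment and differentiation shifted upward, with 20 of 30 higher (median 0.32, camera adjusted p = 0.0228; adjusted p = 0.223 with an estimated correlation and 0.131 by fry; samples apart in 16.7%). The commitment factors Myod1 (0.07) and Myog (-0.30) were not among those that led it, which were the membrane genes Sgca (0.83) and Dmd (0.41), the myosin Myh8 (0.88) and the calcium store protein Casq2 (1.26). In limma 0 passed over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05. The median was 0.22 within slide 1, where the shift did not pass (adjusted p = 0.0674), 0.31 within slide 2 and 0.32 with slide as a block. The call was lost without WT sample 1 or 2 (adjusted p = 0.0954 and 0.114) and without KO sample 2 or 3 (adjusted p = 0.136 and 0.0683), in a range from 0.0011 to 0.223 over all alternatives. Myofibre markers moved the same way in these samples (median 0.31).

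Among signalling pathways Wnt genes shifted upward, with 28 of 38 higher (median 0.20, camera adjusted p = 0.000642; adjusted p = 0.0841 with an estimated correlation). Over all genes limma called 0, 8 had an unadjusted p under 0.05, and adjusted over the list alone 4 were higher and 1 lower. Those higher included the secreted inhibitors of Wnt Sfrp1 (1.66), Dkk3 (1.69) and Sfrp2 (1.10), and the ligand Wnt4 was lower (-1.86). Markers of fibro-adipogenic progenitors (median 0.80) and matrix genes (median 0.58) were higher in the same samples. Samples were apart in 18.4%, and the median was 0.13, 0.23 and 0.19 in the 3 slide settings. Notch genes did not shift, with 13 of 28 higher (median -0.04, adjusted p = 0.355; samples apart in 14.3%; -0.08, -0.06 and -0.04 in the slide settings). Limma called 0 over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05, Hey2 (-0.91) and Dll1 (-0.52), with Heyl at -0.35 and Hes1 at 0.38. TGF-beta and BMP genes did not shift either, with 21 of 33 higher (median 0.07, camera adjusted p = 0.0936). Samples were apart in 24.2%, and the median was 0.06, 0.10 and 0.08 in the slide settings. The list passed under 6 of 31 alternatives, among them quantile normalization (camera adjusted p = 0.0446). Another was fry (adjusted p = 0.0309), which does not compare the genes with others. The adjusted p ranged from 0.0309 to 0.395 over all alternatives. By limma, 0 members passed over all genes, 3 had an unadjusted p under 0.05, and the activin subunit Inhba (1.35) passed adjusted over the list alone. Bmp7 gave 1.29, Tgfbr2 0.31 and Tgfbr3 -0.34.

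Imprinted genes shifted upward, with 20 of 28 higher (median 0.25, camera adjusted p = 0.000441; adjusted p = 0.255 with an estimated correlation; samples apart in 39.3%). The growth factor Igf2 rose by 1.30 ± 0.12 (limma adjusted p = 0.0442), and the matrix proteoglycan Dcn (0.92), also a marker of fibro-adipogenic progenitors, passed with it adjusted over the list alone. Slc38a4 gave 1.33 and Gatm 0.62. The median was 0.35 within slide 1, 0.06 within slide 2 and 0.22 with slide as a block.

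In all, 32 lists were tested with a preset correlation of 0.01 between genes. Of these 21 shifted, 15 upward and 6 down, and 0 did with a correlation estimated for each list, where 7 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0786. For each shifted list except the ribosomal proteins that was the highest adjusted p of all alternatives. By limma's fry, which asks whether a list's genes move one way without comparing them with other genes, 11 lists moved upward and 0 down. Of the 21 shifted lists 8 were among these 11. Not among them were all 6 that shifted down, and the endothelial, pericyte, tenocyte, myofibre, myogenic, p53 and interferon lists. Within slide 1 and with slide as a block 21 and 19 lists shifted. With all arrays kept separate, sample as a random block and slide as a fixed block, 21 did.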

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

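The fits of all 9 arrays and those without a whole KO sample were chosen after the data were seen. Signal over background limits the folds of dim genes: 10 of the 40 genes called had a WT level not well above background. The count of changed genes was 295 after normexp and the 75th percentile (249 higher, 46 lower), 249 after normexp and quantile normalization (212, 37), 248 in the deposited table (211, 37) and 384 with a trended and robust prior (323, 61), and they shared 32, 33, 33 and 35 with the 40. It was 18 when centred on the median (17, 1), 13 with no filter (13, 0), and 103 with the filter on all arrays of a group (92, 11). With slide as a block, a term set by the WT samples alone, it was 4. With all 9 arrays it was 1202, and 546 with the sample as a random block and 367 with slide as a fixed block too. It was 0 to 1 without a WT replicate, 25 to 47 without a KO array and 1 to 9 without a KO sample (5 and 9 without samples 1 and 2). It was 0 with KO replicate 1 as WT (limma, 1189 at an unadjusted p under 0.05), which mixes one KO sample into both groups. Fewer samples or terms for blocks leave fewer degrees of freedom, and fits of all 9 arrays gain some from paired arrays. Otherwise the cause was not tested.

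Cdkn2a kept its direction under all alternatives (2.46 to 3.48, limma adjusted p from 8e-05 to 0.965) but missed the threshold with slide as a block (3.33), without a WT replicate (3.17 to 3.48), without a KO sample (3.18 to 3.36), with KO replicate 1 as WT (2.48) and with both replicate blocks. Bmi1 stayed between 0.0009 and 0.16 and never passed. The numbers did not pair the samples, since deviations of same-numbered samples correlated at -0.043, 0.025 and 0.008. With a replicate block by title or description the count of genes was 0 (limma, 2818 and 2950 at an unadjusted p under 0.05) and Cdkn2a gave 3.28 and 3.28 without passing (adjusted p = 0.162 and 0.173), with degrees of freedom lost to the block.

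The lists shifted numbered 17 to 22 under all alternatives except an estimated correlation (0) and fry (11). Directions reversed, all without a call, for Bpgm without WT replicate 2 (-0.0151, and up to 0.22 without another), Rpl21 with the mean of its probes (-0.24), the Polycomb subunits without KO sample 3 (adjusted p = 0.828, from 0.0707 over all alternatives) and the erythroid markers with no filter (0.856), without WT replicate 1 (0.816), with KO replicate 1 as WT (0.83) and without KO sample 2 (0.804), in a range from 0.344 to 0.915 over all alternatives. The cause was not tested. Over the 135 other named genes, 3479 of 3913 values under the alternatives kept direction and side of the threshold, 160 lost a call and 272 gained one, and for the lists these were 902, 61 and 24 of 992.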

Other observations

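The tests on splits of the samples were set before the data were examined, while all tests of the endothelial, G2/M and Hox patterns were chosen after these results were seen. Of 65 measured genes of oxidative phosphorylation, 60 were lower (median -0.13, camera adjusted p = 0.000244; adjusted p = 0.546 with an estimated correlation), such as Sdhc (-0.30), Cyc1 (-0.36), Atp5b (-0.18) and Ndufa9 (-0.27). Of 74 cytosolic ribosomal protein genes, 64 were lower (median -0.07, adjusted p = 0.0177; adjusted p = 0.674 with an estimated correlation), such as Rpl18 (-0.14) and Rps18 (-0.17), with Rpl21 at 0.27. By limma, 0 genes of either list passed over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. The medians of WT samples 1, 2 and 3 and KO samples 1, 2 and 3 were 0.05, -0.16, 0.10, -0.105, -0.05 and -0.18 for the first list and 0.04, -0.13, 0.08, -0.04, -0.05 and -0.10 for the second, so the groups overlapped. Samples did not overlap in 9.23% and 2.7%, under the 16.7% of all genes and the 10% of chance. Within slide 2 both medians were above 0 (0.04 and 0.06), as compared to -0.21 and -0.13 within slide 1 and -0.09 and -0.04 with slide as a block. The first shift was lost without WT sample 3 (adjusted p = 0.0749) or KO sample 3 (0.06), in a range from 4.1e-08 to 0.546 over all alternatives. The ribosomal one was lost without WT sample 1 (0.0711), WT sample 3 (0.646) or KO sample 3 (0.27), with slide as a block (0.177) and with quantile normalization (0.997), in a range from 1.42e-05 to 0.997.

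Of 39 antioxidant and metal response genes, 19 were higher and 20 lower, and the list did not shift (median -0.03, mean 0.14, camera adjusted p = 0.195, samples apart in 25.6%), though it did without KO sample 3 (adjusted p = 0.0179), after normexp and quantile normalization (0.0442) and in the deposited table (0.0465), in a range from 0.0179 to 0.565 over all alternatives. Its median was against its mean and test in sign, and its slide medians were -0.08, 0.08 and 0.01. In limma 0 passed over all genes, 7 had an unadjusted p under 0.05, and 4 passed adjusted over the list alone, the metallothioneins Mt1 (1.04), Mt2 (0.75) and Mt3 (0.79) and the detoxifying enzyme Gstm2 (0.97). Interferon response genes shifted upward, with 20 of 28 measured members, of 35 listed, higher (median 0.20, adjusted p = 0.0229; adjusted p = 0.546 with an estimated correlation; samples apart in 7.14%). KO sample 1 carried it (medians 0.66, 0.06 and 0.00 in KO samples 1, 2 and 3), and it was lost without that sample (adjusted p = 0.457), without WT sample 1 (0.134) or 3 (0.14) and with slide as a block (0.18, adjusted p = 0.107), in a range from 0.000854 to 0.546 over all alternatives, with medians of 0.29 and -0.01 within slides 1 and 2. Ifit1 gave 2.79 (at least 3.0-fold on background-subtracted signal, and 0.66 after normexp), Stat2 0.54, Mx2 1.15 and Ifih1 0.75. In limma 0 of them passed over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05. Autophagy and lysosome genes did not shift (17 of 30 higher, median 0.05, adjusted p = 0.446, samples apart in 10%), with Map1lc3a at 0.32 and Uvrag at -0.40. In limma 0 passed over all genes or adjusted over the list alone, 0 had an unadjusted p under 0.05, and the slide medians were 0.08, 0.02 and 0.04.

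The 6 samples make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 40 genes and the highest other split 3, and the real split gave 21 lists and the highest other 16. In each case 1 split, the real one, reached the real value. The other splits gave 11, 11, 16, 13, 12, 10, 0, 6 and 6 lists. Camera at the preset correlation thus also called lists with the groups mixed, though each split still held WT and KO samples in unequal numbers.

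Endothelial markers were higher in KO although the gate removed CD31-positive cells. A lower share of satellite cells would raise the markers of every other cell type alike. The endothelial median exceeded the myeloid one by 1.35 (95% interval over resampled genes 0.621 to 2.188). It exceeded the lymphoid one by 1.41 (0.688 to 1.865). These differences cannot decide the question, since the gate also removed CD45-positive and CD11b-positive blood cells. The intervals also resample genes, which move together, and not samples. RNA of endothelial cells that passed the sort in a share that differs between samples cannot be told apart from genes regulated together: the markers' correlation between samples (0.433) lay above that of all 200 random lists matched on level (percentile 100), but 5 of the 31 other lists, such as G2/M genes (0.714), had a higher one. Members moved by different amounts, Fabp4 by 2.30, Ly6c1 by 1.70 and Kdr and Tek by 0.17 each, and Tek stands in the satellite cell list as well. A change of the satellite cells themselves was not tested and stays open, for these and for the mesenchymal, glial and mural markers that were higher too.

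G2/M genes were lower in KO to a different extent in each sample. A difference between the 2 slides is argued against by the medians of -0.95 within slide 1 and -0.99 within slide 2, which holds 1 WT array. The median was -1.0 with slide as a block, but that term is set by the WT samples alone. Whether KO sample 3 alone sets the size cannot be told apart from an effect in all. Without it the median was -0.71 (camera adjusted p = 4.41e-13 with the preset correlation). Over all samples the list did not pass with an estimated correlation (camera adjusted p = 0.255) or by fry (adjusted p = 0.102). KO sample 1, at -0.90, also lay well below the lowest WT sample, at -0.179. KO sample 2, however, lay only 0.184 below that WT sample, where the WT samples span 0.329. The share of cycling cells in each sort was not measured, so fewer dividing cells in the KO samples, by genotype or by sample, stay open as explanations.

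Hox genes of high number may have risen while those of low number fell in KO, as position in the cluster would give. Across the 33 measured genes the number and the change had a Spearman rho of 0.44 (Pearson 0.539, permutation p = 0.0118). With numbers permuted within each cluster the permutation p was 0.00179. Among the 25 genes well above background on all arrays the trend did not pass (rho 0.278, permutation p = 0.178). The trend thus leans on genes dim on some arrays, and the filter admits such genes more easily when they are higher in KO. Genes of a cluster are neighbours and not independent, so these p are too small, and position stays a candidate explanation. No technical explanation was tested for it.

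All 9 arrays were labelled male. The X-inactivation transcript Xist was well above background on 9 of 9 arrays, with a log2 signal from 5.59 to 5.83. The probes of the Y-linked genes Ddx3y, Kdm5d and Uty were so on 0 of 9 arrays, and that of Eif2s3y on 9 of 9, at a mean of -1.89. Of 149 probes placed on the Y chromosome, 86 (57.7%) were well above background on 0 arrays, as compared to 17.2% of all probes, and 36, that of Sry among them (mean -0.28), on all 9. The 86 included the probes of Usp9y, Zfy1 and Zfy2. Xist and the Y-linked genes not above background argue against the male label. The probes of Eif2s3y and Sry go the other way, and what they bind was not tested. The sex of the samples thus stays uncertain.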
